A study of Arabidopsis thaliana with 12 samples.

How the data were processed

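Small RNA from inflorescences of Arabidopsis thaliana was sequenced in 12 libraries: 3 biological replicates each of the wild type Col-0 and of the mutants heso1-1, urt1-1 and ntp4-1. Per the labels' protocols, plants were grown with 16 h of light and 8 h of dark at 22 °C, RNA was extracted with TRIzol and treated with DNase I, and libraries were made with the NEBNext small RNA kit. The labels call the replicates biological, so p-values measure the spread between plants or pools of plants, as far as that word goes. The aligner, the genome build and the treatment of reads that match several places are not given in the sources used here.

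The authors deposited a single table of 152484 bins of 100 bp with 12 columns of RPM (read counts scaled to library depth) and with the genes, promoters, transposable elements and mature miRNAs they placed in each bin. No other column of values was found in it (0 columns). The bins listed hold only part of each library: their RPM sum to between 28.7% (ntp4-1 replicate 1) and 67.5% (Col-0 replicate 2) of the total that the scaling assumes, so the deposited RPM are relative to reads that are in part outside the table. In 11 of the 12 columns every value was a whole multiple of the worth of 1 read (100% of values, within a tolerance of 1e-06), which gives implied totals of 2761330 to 11191516 reads per library and 1632520 to 6647319 reads in the listed bins. For Col-0 replicate 3 the worth of 1 read, about 0.101 RPM, lies so close to a decimal rounding step that whole reads were not claimed, and that library is absent from the tests on reads. Intervals are not given for single libraries, because sequenced reads without molecular identifiers are not independent molecules.

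Coordinates are the authors' bin positions. They were compared with the reference TAIR10.1: 99.46% of the gene listings on the nuclear chromosomes overlapped the gene of that name in the reference, and 9120 of 9247 nuclear gene identifiers were found there, so gene ends and gene types were taken from that reference. The mitochondrial sequence differs in length, so mitochondrial genes keep the authors' bins. Loci were built by adding the RPM of the bins whose midpoint lies in the annotated gene, or, where there was none, of the bins that overlap it, which gave 11153 loci. A short precursor can therefore lack an arm: the MIR165a locus is its 3p bin alone, and the MIR159b locus (7.89 ± 4.67 RPM in Col-0) lacks its 3p bin (2623 ± 730 RPM). Bins carry no strand, so overlapping and antisense genes cannot be told apart, and loci that share bins are named together. Near-identical loci, such as members of a MIR family with the same mature sequence, are uncertain, because placement of their reads is not known.

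Groups were compared with limma (version 3.58.1, R 4.3.3), trend on, on log2(RPM + 0.5) as deposited, over bins or loci with a mean of at least 1 RPM in the 6 libraries of a comparison, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are therefore on the log2(RPM + 0.5) scale, which understates the change of low loci, and each comes with its standard error (SE); RPM are given as mean ± SD of 3 libraries. Adjusted p-values of bins, loci and arm ratios are from limma, and those of lists are from camera, limma's competitive test of a set against the other loci, with its preset correlation. Camera with an estimated correlation and fry, which asks whether the genes of a set move one way on balance, were run beside it. Whole reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as alternatives. The written design had assumed that only heso1-1 and Col-0 would be in the table; the columns of urt1-1 and ntp4-1 were matched by name to their labels and given the same tests, which that design foresaw.

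The 14 lists of loci were written, with the tests and the rule for naming loci, before the data were examined: all MIR genes; conserved MIR families; developmental, nutrient and stress MIR families; MIR families that target the small RNA machinery; trans-acting siRNA (TAS) loci; triggers of phased siRNAs; pentatricopeptide repeat (PPR) genes with phased siRNAs; rRNA, tRNA, snRNA and snoRNA genes; chloroplast genes; mitochondrial genes; pollen MIR genes; nuclear protein-coding genes; and transposable element genes. Chloroplast genes stand for green tissue and pollen MIR genes for another cell type of the inflorescence. The naming rule took called loci with no overlap between the groups (the 10 largest rises and the 10 largest falls), called members of the shorter lists, the 5 MIR genes and the TAS loci with the highest mean, and, where fewer than 5 loci were called, the 10 smallest p-values in each direction. For bins it took the 5 largest rises and falls, joined with called neighbours. Values given for joined bins are those of the single bin with the largest change. The remaining called loci of urt1-1 are named because they were called, and list members outside this rule were chosen after their values were seen. A locus that the rule names in ntp4-1 is not reported.

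Shares of the listed RPM in the chromosome arms, pericentromeres, chloroplast and mitochondrion were compared by exact permutation tests, two-sided, where 3 against 3 libraries cannot give a p below 0.1. The ratio of the bin holding the 3p arm to the bin holding the 5p arm of a miRNA precursor was tested with limma on log2 values. That test was added after the data were seen. It was first run on 33 precursors without asking that each annotated mature sequence lie whole in its bin; that requirement was added after its calls were seen and left 30 precursors.

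Replicates with the same number were compared by the correlation of their deviations from the group means over bins, to see whether the numbers pair the libraries. The correlations were 0.57, 0.25 and 0.19 for Col-0 and heso1-1, 0.65, 0.38 and 0.32 for Col-0 and ntp4-1, and 0.58, 0.22 and 0.20 for heso1-1 and ntp4-1, all above the limit of 0.1, so these numbers were taken as pairs on the basis of the values alone, since no label says so. The pairing is weak for Col-0 replicate 3, which correlated better with replicate 2 of heso1-1 (0.22) and of ntp4-1 (0.34) than with replicate 3. It is weak too for heso1-1 replicates 2 and 3, which correlated better with the other number of ntp4-1 (0.27 and 0.29). Col-0 replicate 2 correlated as well with replicate 3 of heso1-1 (0.25) and of ntp4-1 (0.38) as with replicate 2. The limit of 0.1 could therefore not tell how replicates 2 and 3 pair. Results with the replicate block rest on an assumed pairing. With the replicate block the number of changed bins was 14 in heso1-1 and 10933 in ntp4-1, against 23 and 30 without it, and for named results whose call it changes the blocked value is given. No 2 libraries of a group were copies of each other: at most 23667 of 152484 values were the same. The first component of variation within groups took 62.9% of that variance and set 5 libraries apart from the other 7: Col-0, heso1-1 and ntp4-1 replicate 1 and urt1-1 replicates 1 and 3. These are called library sets A and B; they were defined from the values and no label names them.

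Alternatives were other pseudocounts, filters, scalings (TMM and median ratio), the replicate block, each library left out, and the tests on reads. Scaling to listed reads, the library set as a term or as a subset, and the arm test with all its settings were added after the data were seen. The tests were tried on simulated data with independent residuals, which is optimistic. Of 100 bins changed 4-fold in the 43648 bins of the heso1-1 comparison, 16% were recovered, and of 100 changed 16-fold, 98%. In the urt1-1 comparison (41906 bins) these shares were 17% and 97%, and in the ntp4-1 comparison (39696 bins) 6% and 80%. For loci, 4-fold changes were recovered at 53% (heso1-1, 6969 loci), 55% (urt1-1, 6943 loci) and 40% (ntp4-1, 6763 loci), and 16-fold changes at 98%, 97% and 94%. False calls numbered 12, 7 and 2 for bins and 11, 9 and 10 for loci, in the same order. In each comparison 0 of 20 random lists were called and the shifted list was recovered. Arm ratios were simulated with 1 fixed spread that was not taken from the data. There 10 of 10 shifted arm ratios of 30 were recovered, with 0, 1 and 0 false calls. Among the 33 precursors tested first, SE reached 1.65 in heso1-1 and 2.32 in urt1-1. The simulation therefore does not show how many real arm shifts would be found. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.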

Results

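Small RNA was profiled in inflorescences of Arabidopsis thaliana, in the wild type Col-0 and in the mutants heso1-1, urt1-1 and ntp4-1, with 3 biological replicates in each of the 4 groups. HESO1 (AT2G39740) and URT1 (AT2G45620) are uridylyltransferases that add U to the 3' ends of RNA, among them miRNAs that lack 3' methylation. The series asks how NTP4 shapes miRNA levels through the 2 strands of the miRNA duplex. Values were RPM, read counts scaled to library depth, in 152484 bins of 100 bp. In the 11 libraries where whole reads could be recovered the implied totals were 2761330 to 11191516 reads, the lowest being heso1-1 replicate 3. The listed bins held 52.2%, 67.5% and 63.7% of the reads in Col-0 replicates 1 to 3 and 28.7%, 48.5% and 54.3% in ntp4-1. Positions below are in the authors' coordinates, which matched TAIR10.1.

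Small RNA values are not a measure of the mRNA of a mutated gene, so the mutated loci do not check the labels. No bin was listed in the gene body of HESO1 or anywhere at URT1. The promoter of HESO1 had 5 listed bins between positions 16574701 and 16575300 of chromosome 2, which summed to 4.54 ± 3.38 RPM in Col-0 and 4.53 ± 2.10 RPM in heso1-1 (SD, n = 3).

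The median bin lay below Col-0 in every mutant, with a log2 fold change of -0.23 in heso1-1, -0.40 in urt1-1 and -0.75 in ntp4-1 on the deposited scale, and of -0.04, -0.02 and -0.11 after TMM scaling. The median locus was at -0.30, -0.41 and -0.80. Changes of lists are therefore given relative to the median of all loci tested, and those of single loci as deposited.

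The first comparison asked which small RNAs differ without HESO1. The locus of AGL23 (AT1G65360, a MADS-box gene that acts in embryo sac development; chromosome 1, 24281337 to 24282233) rose from 0.381 ± 0.545 RPM in Col-0 to 36.6 ± 9.46 RPM in heso1-1 (SD, n = 3), a log2 fold change of 5.53 (SE 0.45, adjusted p = 0.0035). Most of the AGL23 signal lay in 1 bin that also overlaps a transposable element, with means of 35.4, 43.55 and 17.4 RPM in heso1-1, urt1-1 and ntp4-1. AT3G09960 (chromosome 3, 3061945 to 3063594) rose from 0.247 ± 0.316 to 25.6 ± 11.6 RPM, a log2 fold change of 5.12 (adjusted p = 0.0035). The transposable element gene AT3G22955 (chromosome 3, 8138497 to 8138965) fell from 64.9 ± 31.6 to 1.14 ± 0.374 RPM, a log2 fold change of -5.20 (adjusted p = 0.0035). AT5G42410 (chromosome 5, 16964650 to 16965261) stood at 4.83 ± 1.23 RPM in Col-0 and was listed at 0 in all 3 heso1-1 libraries (adjusted p = 0.0308). These were the 4 loci called among 6969, with 788 at an unadjusted p under 0.05. With the replicate block the count was 0, with 1584 at an unadjusted p under 0.05. The adjusted p of the first 3 was then 0.0618 and that of AT5G42410 0.114. Without heso1-1 replicate 1 the count was 11 and without heso1-1 replicate 3 it was 9, while edgeR on the recovered reads called 2 loci and DESeq2 65.

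Other loci in heso1-1 are given as values, because none passed the test. MRD1 (AT1G53480) stood at 4.09 ± 0.590 RPM in Col-0 and 17.4 ± 1.95 RPM in heso1-1 (adjusted p = 0.0906, and 0.0279 after TMM scaling). It shares bins with AT1G07887 and HEI10 (AT1G53490), a gene of meiotic crossover formation. AT1G28000 was at 4.26 ± 0.844 and 28.0 ± 12.2 RPM (adjusted p = 0.0922), AT5G44770 at 0.189 ± 0.0929 and 11.8 ± 10.8 RPM. AT2G00840 was at 1.06 ± 0.272 and 5.97 ± 0.477 RPM, and AT2G31140 at 1.58 ± 0.284 and 7.17 ± 2.66 RPM. On the lower side, AGL12 (AT1G71692), a MADS-box gene of root development, was at 5.63 ± 2.43 RPM in Col-0 and 0.121 ± 0.209 RPM in heso1-1 (adjusted p = 0.0922). AT5G42567 was at 84.5 ± 12.4 and 34.1 ± 0.703 RPM, and the chloroplast locus ATCG00410 at 138.5 ± 13.8 and 40.4 ± 15.1 RPM. The tRNA locus AT4G28362 and the bins shared by AT5G45715 and AT5G45720 were listed at 0 in heso1-1 against 4.31 ± 2.22 and 5.71 ± 4.09 RPM in Col-0. AT2G19200 was at 11.1 ± 2.99 and 0.945 ± 0.840 RPM (adjusted p = 0.142), AT5G34882 at 0.168 ± 0.290 and 6.48 ± 3.33 RPM (0.113) and the tRNA locus AT5G35605 at 9.45 ± 4.95 and 1.05 ± 0.482 RPM (0.24).

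Among single bins, 23 of 43648 changed in heso1-1, 9 up and 14 down, with 2708 at an unadjusted p under 0.05. After TMM scaling the split was 3 up and 10 down, and with the replicate block 2 up and 12 down. The bin at 24281401 to 24281500 of chromosome 1, in AGL23 and a transposable element, rose by 5.48 on the log2 scale (adjusted p = 0.00091). Of 2 joined bins at 3063401 to 3063600 of chromosome 3, in AT3G09960, the leading one rose by 4.79. For other joined bins, too, values here and below are those of the leading bin. In AT4G13420, the bins at 7799501 to 7799700 of chromosome 4 rose by 3.75 (adjusted p = 0.0366, and 0.0781 with the replicate block). The block also ended the call of 2 other rises. 1 was at 18458101 to 18458200 of chromosome 1, in a transposable element in the promoter of AT1G49860 (3.75, adjusted p = 0.0126 and then 0.0605, and 0.0617 after TMM scaling). The other was at 13196001 to 13196100 of chromosome 5 in AT5G34882 and transposable elements (adjusted p = 0.0432 and then 0.0726, and 0.118 after TMM scaling). The falls were at 8138601 to 8138800 of chromosome 3 in AT3G22955 (log2 fold change -6.32), at 566801 to 566900 of chromosome 4 in the promoter of AT4G01370 (-5.93). Others were at 10860401 to 10860500 of chromosome 4 in the promoter of AT4G20070 (-5.82), and at 11010901 to 11011000 of chromosome 2 between genes (-4.97). A bin at 15949601 to 15949700 of chromosome 5, in a transposable element and the promoter of AT5G39850, was at 23.5 ± 0.322 RPM in Col-0 and was listed at 0 in heso1-1. The count of bins was 13 without Col-0 replicate 2 and 12 without Col-0 replicate 3. In the count tests edgeR called 0 bins, with 1624 at an unadjusted p under 0.05, and DESeq2 94.

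In heso1-1, 9 of 14 lists passed by camera, and 0 with an estimated correlation and 0 by fry; other splits of the same libraries gave up to 8. The 71 tested loci of conserved MIR families had a median log2 fold change 0.91 above that of all loci (adjusted p = 8.14e-13 by camera), the 40 developmental ones 0.94 (1.84e-11), the 13 nutrient and stress ones 1.22 (0.000146) and all 213 MIR genes 0.42 (5.48e-08). None of these calls held with an estimated correlation, where the adjusted p = 0.427, 0.427, 0.4 and 0.515 in the same order. No MIR gene passed on its own (0 of 213 by limma over all loci, and 0 adjusted over the list alone for all MIR genes). Within the nutrient list the count was 1 when adjusted over the list alone: MIR827, which acts in phosphate starvation, at 3.75 ± 2.86 RPM in Col-0 and 42.1 ± 32.6 RPM in heso1-1. The copper-linked MIR408 stood at 1.95 ± 1.31 and 5.31 ± 0.643 RPM, and MIR398b at 4.85 ± 4.68 and 23.7 ± 20.1 RPM. Of 5 abundant MIR loci 4 overlapped Col-0: MIR158a was at 9783 ± 4129 and 9791 ± 4159 RPM, MIR159a at 4061 ± 1073 and 5515 ± 2687 RPM, MIR166a at 1938 ± 493 and 3548 ± 2809 RPM and MIR780 at 1197 ± 161.5 and 1278 ± 593 RPM. MIR319c was at 2454 ± 981 and 1285 ± 410 RPM, without overlap (adjusted p = 0.429).

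The other lists in heso1-1 follow. The rRNA, tRNA, snRNA and snoRNA genes stood 0.60 above all loci (camera adjusted p = 2.43e-14), chloroplast genes 0.39 (2.94e-05), mitochondrial genes 0.22 (0.00282) and nuclear protein-coding genes 0.10 (0.00453), and transposable element genes were at -0.14 (3.47e-12). With an estimated correlation these 5 calls were lost (adjusted p = 0.4, 0.598, 0.515, 0.598 and 0.515). On the deposited scale the median mitochondrial and protein-coding loci were at -0.08 and -0.20 and after TMM scaling at 0.20 and 0.08. Among 2425 protein-coding loci 2 rose and 1 fell, and 6 and 2 when adjusted over the list alone; among 2810 transposable element genes 1 fell, as it did adjusted over the list alone, and 809 had all heso1-1 libraries below all Col-0 libraries. Groups did not overlap at 22.0% of all loci, 210 above and 1325 below. The 10% expected by chance is no reference for this share. The scale of a library moves all loci together, and the median locus lay lower as deposited. The TAS loci (7 tested, 0 called, camera adjusted p = 0.189) included TAS1C at 4079 ± 281 and 2256 ± 419 RPM and TAS1B at 442 ± 86.7 and 219 ± 123 RPM. TAS1A was at 871 ± 257 and 713 ± 210 RPM, TAS2 at 2349 ± 564 and 1986 ± 781 RPM and TAS3 at 498 ± 249 and 515 ± 251 RPM. The MIR families that target the small RNA machinery (adjusted p = 0.391) had a median of 0.04 and a mean of -0.04, the PPR genes had 0.391, and the triggers of phased siRNAs had 0.0606, which became 0.019 with the replicate block. The 3 pollen MIR genes (0.391) had a median log2 fold change of -1.40 under a test that pointed up. MIR2939, the 1 of them past the threshold when adjusted over the list alone, was at 0.390 ± 0.371 and 4.16 ± 2.87 RPM. MIR845a and MIR845b were at 841 ± 888 and 314 ± 285 RPM against 1472 ± 723 and 531 ± 65.2 RPM in Col-0.

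The comparison of urt1-1 with Col-0 asked the same of URT1. Small RNA rose over 24 nuclear protein-coding loci and fell over 3. EBF1 (AT2G25490, an F-box protein of ethylene signalling; chromosome 2, 10847375 to 10850797) rose from 1.08 ± 0.238 to 35.8 ± 7.98 RPM (log2 fold change 4.50, SE 0.29, adjusted p = 0.000965; SD, n = 3). GRF5 (AT3G13960, a growth-regulating factor of leaf cell division; chromosome 3, 4608076 to 4610497) rose from 0.916 ± 0.256 to 42.6 ± 24.2 RPM (4.79, SE 0.42, adjusted p = 0.0033), and AT5G44770 from 0.189 ± 0.0929 to 27.2 ± 10.3 RPM (adjusted p = 0.000965). AGL23 rose by 5.79 and AT3G09960 by 5.31 on the log2 scale, and AT5G34882 by 4.85. BRI1 (AT4G39400, the brassinosteroid receptor kinase) rose by 3.37 (adjusted p = 0.0162), TCP14 (AT3G47620, a TCP transcription factor) by 3.01 (adjusted p = 0.00839), GH9B1 (AT1G70710, an endoglucanase of the cell wall) by 2.98 and XTH9 (AT4G03210, a xyloglucan endotransglucosylase) by 2.66 (adjusted p = 0.0194).

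**Figure D1:**
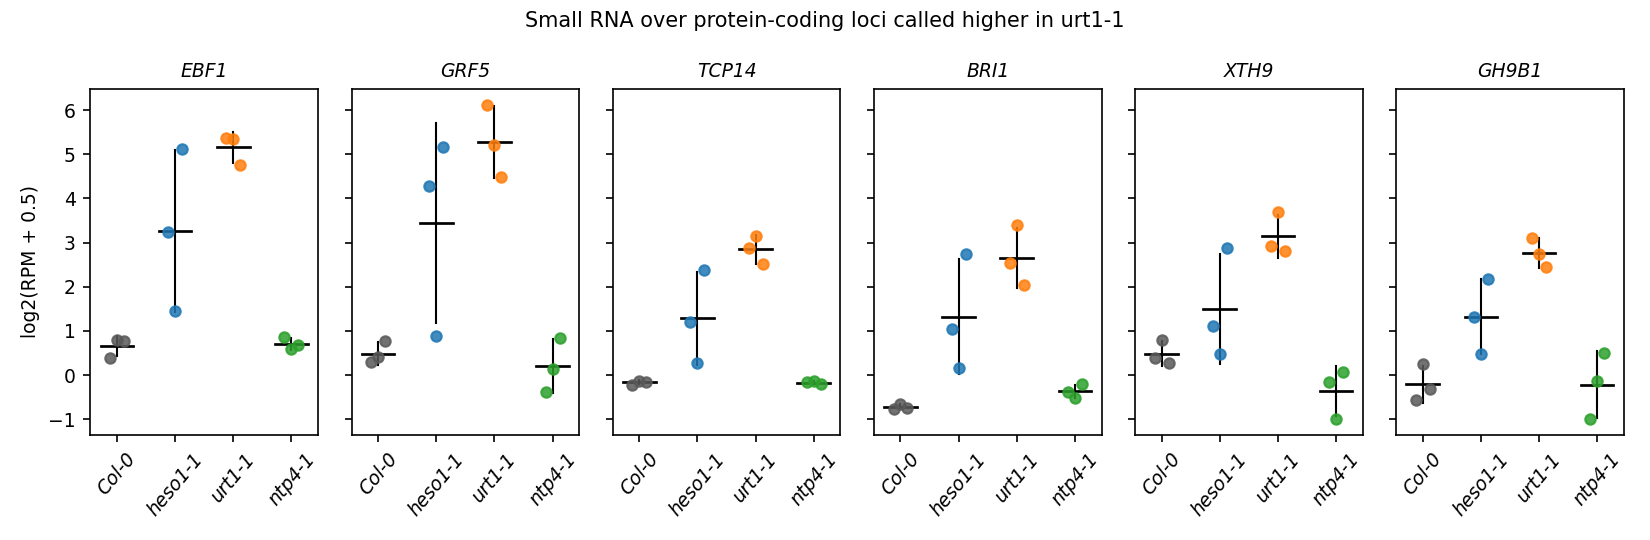
Small RNA over 6 protein-coding loci called higher in urt1-1, as log2(RPM + 0.5) on the vertical axis, for the 4 groups. Points are libraries, horizontal lines group means and vertical lines ± 1 SD (n = 3); EBF1 lies higher in every urt1-1 library than in every Col-0 library, while the heso1-1 libraries spread widely.

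The other rises in urt1-1 were AT5G20700 (3.22), the transposable element gene AT4G03824 (3.15), AT4G29920 (3.00), AT1G28005 (2.91) and AT1G28000 (2.52), which share bins, AT5G16410 (2.82) and AT1G62030 (2.72). Smaller rises were those of AT4G28920 (2.33), AT2G32060 (2.32), AGP9 (AT2G14890, an arabinogalactan protein, 2.31), AT3G17530 (2.16), AT3G57480 (2.06), SAG20 (AT3G10985, 2.01), and GER1 (AT1G72610) with AT1G72600, which share their bins (1.92). AT2G32060, GER1 and AT1G72600 (limma adjusted p = 0.0469) and AT5G16410 (0.0413) were called in 0 of the 6 fits with 1 library left out. Col-0 was at 0.173 ± 0.0325 RPM for AT2G32060 and 0.0635 ± 0.0552 RPM for AT5G16410. The 9 falls included AT3G22955 (log2 fold change -6.42, from 64.9 ± 31.6 to 0.271 ± 0.469 RPM), AT5G21125 (-3.58), AT3G03945 (-3.52), AT5G42410 (-3.28), AT1G75945 and AT3G06955 (both -2.23) and AT2G16832 (-1.60). AT2G19200 was at 11.1 ± 2.99 RPM in Col-0 and was listed at 0 in urt1-1 (adjusted p = 0.00196). MIR843 was the only MIR gene of 209 that passed, over all loci and adjusted over the list alone: it fell from 15.6 ± 1.98 to 3.88 ± 0.706 RPM (-1.88, adjusted p = 0.0261, and 0.0534 after TMM scaling, with a range of 0.00798 to 0.338 over all alternatives). The lower value was not particular to urt1-1. MIR843 was at 3.88 ± 2.30 RPM in heso1-1 and 2.03 ± 0.193 RPM in ntp4-1, every library below every Col-0 library, without passing in either.

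In all, 34 of 6943 loci changed in urt1-1, 25 up and 9 down, with 1232 at an unadjusted p under 0.05; after TMM scaling the split was 71 up and 11 down. All 34 had no overlap between the groups, against 27.7% of all loci (300 above and 1621 below). That share is on the deposited scale, where the median locus lay lower, so the 10% expected by chance is no reference for it. Leaving out 1 library changed the count to 47 (urt1-1 replicate 2, 24 up and 23 down), 22 (Col-0 replicate 1), 11 (Col-0 replicate 2), 9 (Col-0 replicate 3), 12 (urt1-1 replicate 1) or 21 (urt1-1 replicate 3). EBF1, GRF5 and AT5G44770 were called under all 24 alternatives, with adjusted p up to 0.0425, 0.0451 and 0.0425. The libraries fall into 2 sets that no label names, with urt1-1 replicate 2 and Col-0 replicates 2 and 3 in set B; the count was 377 loci with the set as a term, 120 within set B and 17 within set A. On the recovered reads edgeR called 10 loci and DESeq2 123.

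Among 41906 bins, 78 changed in urt1-1, 31 up and 47 down, with 2877 at an unadjusted p under 0.05; after TMM scaling the split was 83 up and 53 down. The rises were led by the bin at 24281401 to 24281500 of chromosome 1 in AGL23 and a transposable element (5.77) and by 3063401 to 3063600 of chromosome 3 in AT3G09960 (5.10). Others were at 16755101 to 16755200 of chromosome 3 between genes (4.50) and at 10741701 to 10741900 of chromosome 3 in a transposable element and the promoter of AT3G28660 (4.15). The bin at 13196001 to 13196100 of chromosome 5, in AT5G34882 and transposable elements, was listed at 0 in Col-0 and was at 17.9 ± 9.76 RPM in urt1-1. The falls were led by 3 joined bins at 1178801 to 1179100 of chromosome 2 in and beside the promoter of AT2G03870. The leading one of them fell from 104.5 ± 8.501 to 0.0432 ± 0.0749 RPM (-7.60, SE 0.35, adjusted p = 7.27e-05). Among the falls were also the bins of AT3G22955 (-6.20). Others were 11834901 to 11835000 of chromosome 2 (-6.13) and 15949601 to 15949700 of chromosome 5 (-5.26). These lie in transposable elements and in the promoters of AT2G27770 and AT5G39850. The bin at 10860401 to 10860500 of chromosome 4, in the promoter of AT4G20070, was at 35.7 ± 9.35 RPM in Col-0 and listed at 0 in urt1-1. Without Col-0 replicate 2 the count of bins was 28, without Col-0 replicate 3 it was 21, and without urt1-1 replicates 1, 2 and 3 in turn it was 24, 123 and 45. The count tests called 1 bin (edgeR) and 199 bins (DESeq2).

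In urt1-1, 7 of 14 lists passed by camera. Protein-coding genes stood 0.11 above all loci (camera adjusted p = 7.86e-06, and adjusted p = 0.758 with an estimated correlation), with 24 of 2461 up and 3 down over all loci and 39 and 10 adjusted over the list alone. The rRNA, tRNA, snRNA and snoRNA genes stood 0.38 above (2.09e-06), chloroplast genes 0.33 (9e-04), nutrient and stress MIR families 0.56 (0.00231), conserved MIR families 0.29 (0.00717) and all MIR genes 0.17 (0.00662), and transposable element genes were at -0.12 (8.35e-11). With an estimated correlation all 7 were lost (adjusted p = 0.703 to 0.758). After TMM scaling the calls of the 3 MIR lists ended too (adjusted p = 0.0584 for the nutrient, 0.139 for the conserved and 0.0669 for all MIR genes), and the median conserved MIR gene moved from -0.12 to 0.26. Without Col-0 replicate 1 the number of lists called was 4. Of 2796 transposable element genes 1 rose and 2 fell, 1 and 1 adjusted over the list alone, and 988 had no overlap and lay below Col-0.

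The other 7 lists did not pass in urt1-1: developmental MIR families and PPR genes (both adjusted p = 0.209), MIR families that target the small RNA machinery (0.275), TAS loci (0.795), triggers of phased siRNAs (0.734), mitochondrial genes (0.209) and pollen MIR genes (0.149). MIR165b was the 1 developmental member past the threshold when adjusted over the list alone, at 78.1 ± 16.6 RPM in Col-0 and 26.9 ± 9.30 RPM in urt1-1, and MIR166a stood at 1938 ± 493 and 815 ± 255 RPM (adjusted p = 0.199). MIR158a was at 13200 ± 1832 RPM, MIR159a at 5050 ± 4712 RPM, MIR319c at 1503 ± 588 RPM and MIR780 at 840 ± 111 RPM. TAS1C was at 3145 ± 678, TAS2 at 1950 ± 530, TAS1A at 678 ± 232, TAS3 at 548 ± 497 and TAS1B at 368 ± 82.1 RPM. The pollen list had a median of -0.48 and a mean of 0.35: MIR2939 was at 0.390 ± 0.371 and 4.67 ± 2.38 RPM (adjusted p = 0.113, the 1 pollen gene past the threshold adjusted over the list alone), MIR845a at 1038 ± 758 and MIR845b at 429 ± 221 RPM.

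In ntp4-1, the mutant of the gene the series is about, the bins with miR165a-3p and miR166e-3p fell relative to the bins with the 5p arm of the same precursor. miR165 and miR166 repress the HD-ZIP III genes of organ polarity. The bin with miR165a-3p (chromosome 1, 78901 to 79000) was at 92.0 ± 24.7 RPM in Col-0 and 10.9 ± 3.56 RPM in ntp4-1, and the bin with miR165a-5p at 30.5 ± 6.54 and 28.2 ± 15.7 RPM (SD, n = 3). The log2 ratio of the 3p to the 5p bin fell by 2.77 (SE 0.38, adjusted p = 0.00895). For miR166e (3p bin at 16775501 to 16775600 of chromosome 5) the ratio fell by 1.86 (SE 0.28, adjusted p = 0.00895), with the 3p bin at 122 ± 23.8 and 41.2 ± 15.6 RPM and the 5p bin at 4.28 ± 0.854 and 5.55 ± 2.75 RPM. For miR168a (chromosome 4, 10578701 to 10578800) it fell by 1.51 (SE 0.30, adjusted p = 0.0247), with the 3p bin at 43.1 ± 17.3 and 13.7 ± 9.33 RPM and the more abundant 5p bin, that of the strand against AGO1, at 73.2 ± 34.7 and 71.6 ± 51.01 RPM.

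**Figure D2:**
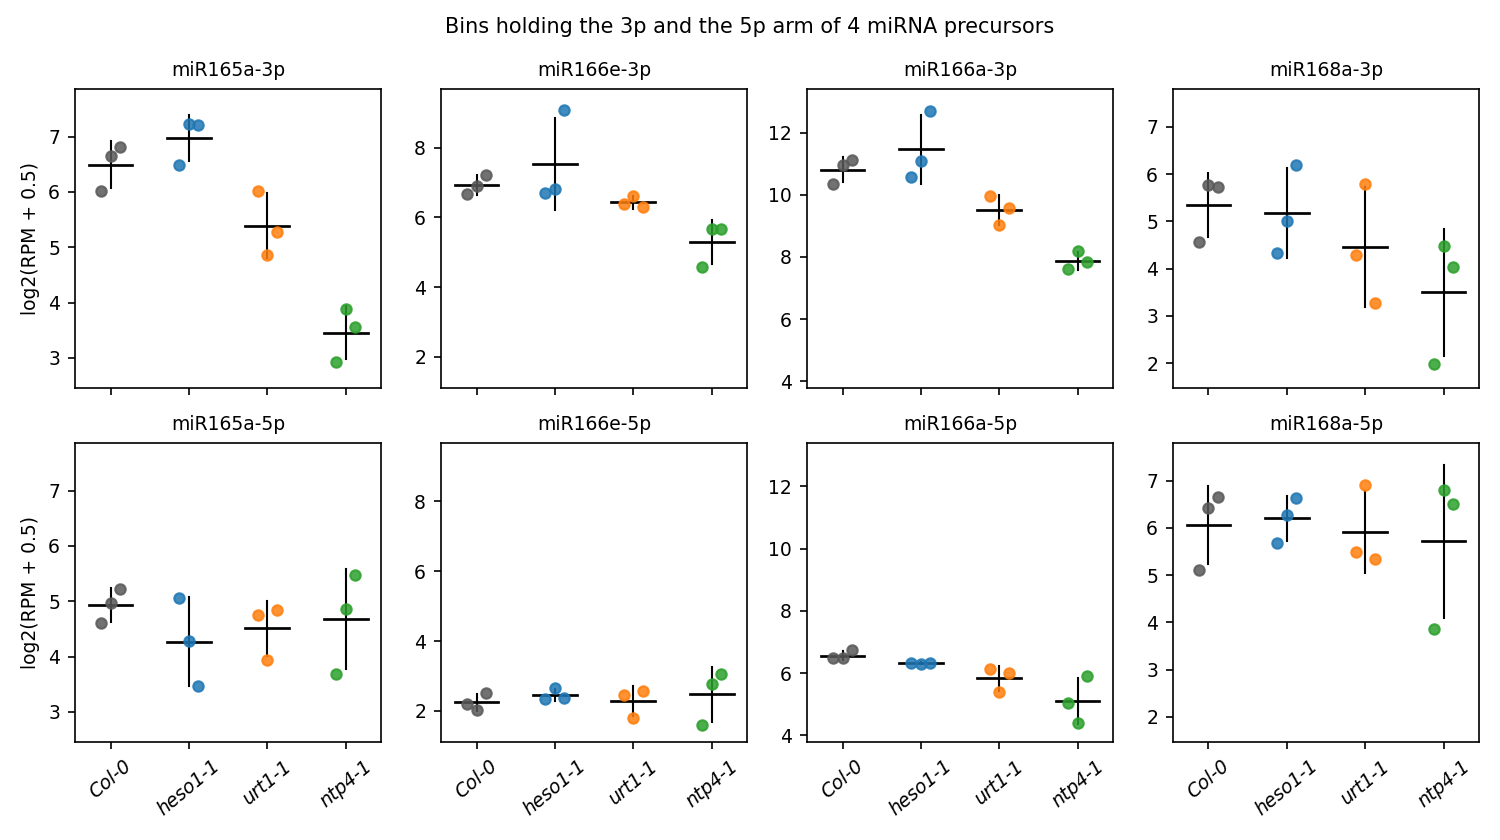
Bins with the 3p arm (upper row) and the 5p arm (lower row) of 4 miRNA precursors, as log2(RPM + 0.5) on the vertical axis, for the 4 groups. Points are libraries, horizontal lines means and vertical lines ± 1 SD (n = 3); every ntp4-1 library lies below every Col-0 library for miR165a-3p, while the miR165a-5p bins overlap.

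For miR171b, which targets GRAS genes, the ratio fell by 2.20 (SE 0.50, adjusted p = 0.0345), with the 3p bin at 16.1 ± 8.14 and 6.27 ± 5.29 RPM and the 5p bin at 1.71 ± 0.777 and 2.98 ± 2.45 RPM. In the other direction the ratio rose by 1.94 for miR156d (SE 0.49, adjusted p = 0.0423), a regulator of SPL genes. Its more abundant 5p bin was at 153 ± 46.98 and 103 ± 46.2 RPM and its 3p bin at 2.21 ± 1.16 and 7.34 ± 6.37 RPM. This rise was not particular to ntp4-1. The miR156d ratio also rose by 2.075 in heso1-1 and by 1.052 in urt1-1, without passing. A direct limma test of ntp4-1 against heso1-1 gave a difference of -0.14 (adjusted p = 0.93). For miR390a, the trigger of TAS3, the ratio rose by 1.13 in ntp4-1 (SE 0.29, adjusted p = 0.0423). Its more abundant 5p bin was at 68.1 ± 40.9 and 33.2 ± 27.02 RPM. The remaining 24 of 30 precursors did not pass, among them miR390b at 1.29 (adjusted p = 0.0917, and 0.0282 with the replicate block) and miR166a at -1.47 (adjusted p = 0.129, and 0.0181 with the replicate block), whose 3p bin was at 1843 ± 486 and 238 ± 50.03 RPM and whose 5p bin was at 94.5 ± 9.73 and 37.1 ± 19.7 RPM. Over all 30 precursors the median ratio change was -0.08, and for the 15 with the more abundant 3p bin it was -0.85. A separate test compared the median log2 ratio of each library, which averaged -0.18 in Col-0 and 0.04 in ntp4-1 over the 30 (exact permutation p = 0.3) and 1.60 and 1.38 over the 15 (exact permutation p = 0.4).

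This arm test was chosen after the data were seen. In its first form, on 33 precursors without asking that the mature sequence lie whole in its bin, 4 were called (miR165a and miR166e with adjusted p = 0.0121, miR168a with 0.0322 and miR171b with 0.0385), and miR156d (0.0522) and miR390a (0.0555) were not, so these last calls depend on that requirement. With the replicate block 14 precursors were called in both forms, and within library set B 14. Without Col-0 replicates 1, 2 and 3 in turn the count was 2, 0 and 0, and without ntp4-1 replicate 2 or 3 it was 3. In heso1-1 and urt1-1 limma called 0 ratios, with 1 and 2 at an unadjusted p under 0.05, but within library set B it called 1 and 11. A direct test found the miR165a ratio lower in ntp4-1 than in heso1-1 by a log2 difference of -3.92 (SE 0.75, adjusted p = 0.0288), the 1 call of that comparison, where the replicate block gave 4 (miR165a adjusted p = 0.000111), and against urt1-1 the difference was -2.09 (adjusted p = 0.0698, 0 calls).

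At whole loci, none of 6763 passed in ntp4-1 by limma, with 1981 at an unadjusted p under 0.05, and the values follow. MIR166a was at 1938 ± 493 RPM in Col-0 and 275 ± 43.9 RPM in ntp4-1 (adjusted p = 0.0627, 0.000392 with the replicate block and 0.0404 after TMM scaling; range over all alternatives 0.000284 to 0.407). MIR165a, whose locus value is that of its 3p bin alone, had an adjusted p of 0.0635 (0.000801 with the block and 0.0322 after TMM scaling). MIR165b was at 78.1 ± 16.6 and 15.6 ± 3.34 RPM (adjusted p = 0.089, 0.00324 with the block and 0.104 after TMM scaling). MIR319c was at 2454 ± 981 and 469 ± 352 RPM (adjusted p = 0.118, 0.000911 with the block and 0.425 after TMM scaling), MIR843 at 15.6 ± 1.98 and 2.03 ± 0.193 RPM (0.0627, 0.00167 and 0.0467), and MIR848, in the bins of AT5G13890, at 69.7 ± 18.3 and 10.6 ± 2.19 RPM (0.0635, 0.00168 and 0.0558). MIR158a was at 9618 ± 6019, MIR159a at 2054 ± 1337 (adjusted p = 0.219, 0.0296 with the block and 0.721 after TMM scaling) and MIR780 at 917 ± 285 RPM. Other low values were those of CYP705A32 (AT3G20950), at 15.0 ± 0.645 and 1.48 ± 0.692 RPM, AT1G26320, at 28.9 ± 2.20 and 5.24 ± 0.522 RPM, AT3G03945, at 6.25 ± 3.21 and 0.0609 ± 0.106 RPM, and the tRNA loci AT3G26747 (27.7 ± 1.25 and 4.16 ± 0.649 RPM) and AT3G61825 (18.4 ± 8.03 and 1.68 ± 0.606 RPM). These 5 passed with the replicate block, with adjusted p = 0.00116, 0.00313, 0.00116, 0.00173 and 0.00116, against 0.0494, 0.108, 0.0322, 0.048 and 0.0963 after TMM scaling.

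Higher values in ntp4-1 were those of AGL23, at 17.9 ± 6.09 RPM against 0.381 ± 0.545 in Col-0 (adjusted p = 0.0627), and AT3G09960, at 19.9 ± 15.0 against 0.247 ± 0.316. Others were those of the tRNA locus AT1G76000, at 15.7 ± 5.602 against 0.180 ± 0.312, AT1G28000, at 16.7 ± 5.54 against 4.26 ± 0.844, and AT1G28005, which shares bins with it, at 9.80 ± 2.27 against 1.51 ± 0.835. AT5G50710 was at 6.68 ± 4.76 against 0.0457 ± 0.0792, AT3G01270 at 4.23 ± 0.821 against 0.527 ± 0.115, and BGAL1 (AT3G13750, a beta-galactosidase) at 3.95 ± 0.461 against 0.842 ± 0.477. The tRNA locus AT1G55625 was listed at 0 in Col-0 and was at 9.69 ± 6.08 RPM in ntp4-1. These 9 passed with the replicate block, with adjusted p = 5.72e-05, 0.000836, 5.72e-05, 0.0152, 0.00544, 0.00343, 0.00881, 0.0186 and 0.000836 in the order given, and after TMM scaling, with adjusted p up to 0.0417.

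The count of 0 loci changed with the replicate block, with TMM scaling and with the libraries included. With the replicate block 1559 loci passed (99 up and 1460 down), after TMM scaling 102 (85 up and 17 down), and with both 333 (273 up and 60 down). Without ntp4-1 replicate 1, whose listed bins hold 28.7% of its reads, 749 passed (178 up and 571 down). With the library set as a term 2853 passed, and within set B 1888. On the recovered reads edgeR called 0 loci, with 759 at an unadjusted p under 0.05, and DESeq2 145 up and 27 down. Groups did not overlap at 41.3% of loci on the deposited scale (126 above and 2667 below). The median locus lay at -0.80 there, so the 10% expected by chance is no reference for this share.

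Among 39696 bins, 30 changed in ntp4-1, 3 up and 27 down, with 7289 at an unadjusted p under 0.05; after TMM scaling the split was 11 up and 14 down. The rises were at 28527701 to 28527800 of chromosome 1 in AT1G76000 (4.59), in the AGL23 bin at 24281401 (4.46), and at 1739101 to 1739200 of chromosome 1 (4.27). All of these bins overlap a transposable element. The falls were led by 6647401 to 6647500 of chromosome 4 between genes, from 103 ± 49.8 to 0.581 ± 0.610 RPM (log2 fold change -6.66). Next was 6594001 to 6594100 of chromosome 1 in a transposable element and the promoter of AT1G19100 (-5.87). Then came 10860401 to 10860500 of chromosome 4 in the promoter of AT4G20070 (-5.68) and 18254601 to 18254700 of chromosome 3 in AT3G49230 (-5.36). The joined bins at 1178801 to 1179100 of chromosome 2, in and beside the promoter of AT2G03870, followed (-5.18 in the leading bin). With the replicate block 10933 bins passed (338 up and 10595 down), and with TMM scaling added 516 (285 up and 231 down). Without ntp4-1 replicate 1 the count was 2924, without Col-0 replicate 1 it was 14, and without Col-0 replicate 2 or 3 or ntp4-1 replicate 2 or 3 limma called 0. The count tests gave 0 bins by edgeR, with 2300 at an unadjusted p under 0.05, and 144 by DESeq2.

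Organelle bins held a larger share of the listed RPM in ntp4-1 than in Col-0. Chloroplast bins held 13.01 ± 0.801% of the listed RPM in ntp4-1 and 6.23 ± 0.256% in Col-0 (SD, n = 3), with every ntp4-1 library above every Col-0 library (exact permutation p = 0.1, the smallest that 3 against 3 allows, adjusted p = 0.1). Mitochondrial bins held 1.87 ± 0.352% and 1.098 ± 0.0481%, and chromosome arms 44.9 ± 2.06% and 50.4 ± 0.0892% (both exact permutation p = 0.1). As deposited RPM the groups overlapped: the chloroplast held 5.65 ± 1.53% in ntp4-1 and 3.82 ± 0.616% in Col-0 and the mitochondrion 0.789 ± 0.1204% and 0.669 ± 0.0639% (both exact permutation p = 0.3). Without the 10 highest bins the chloroplast overlapped as well (4.88 ± 1.795% and 2.34 ± 0.809%, exact permutation p = 0.2). Pericentromeres held 42.3 ± 0.216% in Col-0, 43.2 ± 0.349% in heso1-1, 40.4 ± 0.531% in urt1-1 and 40.2 ± 1.38% in ntp4-1, each mutant apart from Col-0 (exact permutation p = 0.1; adjusted p = 0.4, 0.4 and 0.1). The chloroplast share was 6.42 ± 1.85% in heso1-1 and 8.17 ± 2.99% in urt1-1, overlapping Col-0, and the mitochondrial and arm shares of both overlapped it as well. The rise of the pericentromere in heso1-1 turned to a difference of -2.58 points without the bins at the chromosome 3 rDNA, of which the bin at 14202001 to 14202100 was at 10320 ± 1676 RPM in Col-0 and 19480 ± 2372 RPM in heso1-1. With narrowed pericentromeres the lower values of urt1-1 and ntp4-1 turned to differences of -0.331 and 0.931 points, and both overlapped Col-0.

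**Figure D3:**
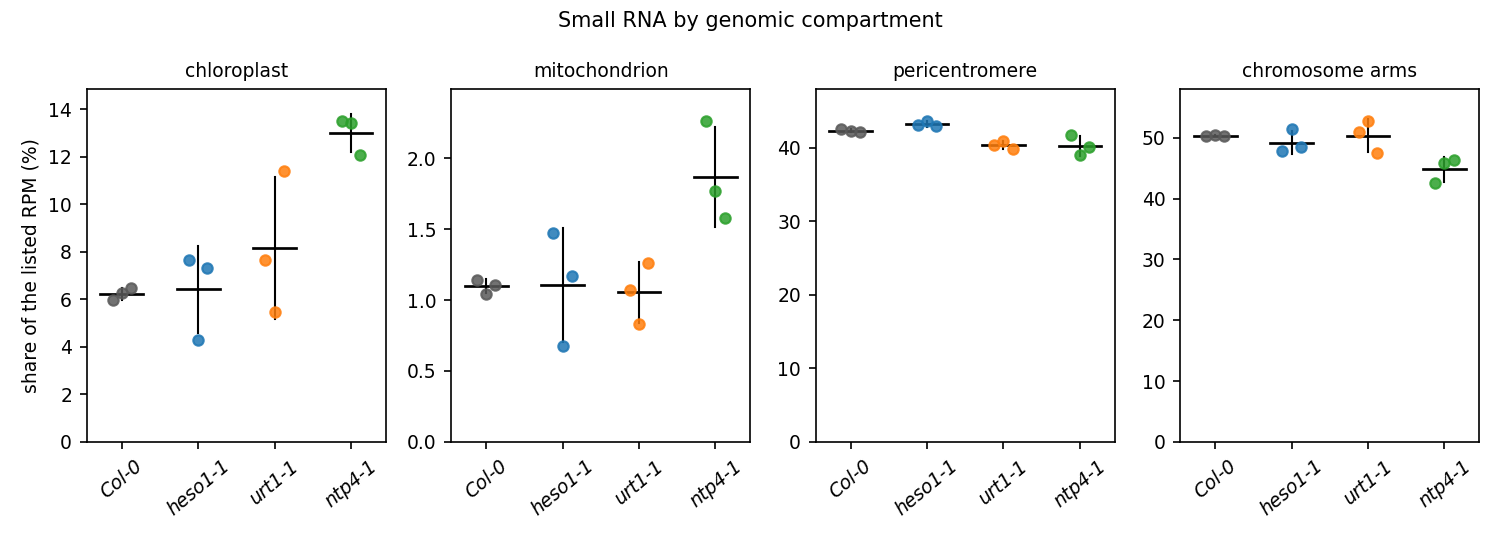
Share of the listed RPM (%) on the vertical axis in the chloroplast, mitochondrion, pericentromeres and chromosome arms, for the 4 groups, each vertical axis starting at 0. Points are libraries, horizontal lines means and vertical lines ± 1 SD (n = 3); the chloroplast share of ntp4-1 lies at 13.01% against 6.23% in Col-0.

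The lists of ntp4-1 stood beside that chloroplast share of 13.01%. Chloroplast genes lay 1.36 above all loci (camera adjusted p = 1.28e-39), rRNA, tRNA, snRNA and snoRNA genes 1.04 (1.91e-27) and mitochondrial genes 0.90 (5.74e-14), and transposable element genes at -0.14 (5.74e-14). With an estimated correlation these were lost (adjusted p = 0.52, 0.52, 0.52 and 0.53). No member of the chloroplast, mitochondrial or transposable element lists passed over all loci or adjusted over the list alone (0 by limma), although 1538 of 2718 transposable element genes lay below Col-0 without overlap. Of 441 structural RNA loci, 2 were higher and 12 lower adjusted over the list alone and 0 over all loci. All MIR genes lay 0.43 above the median locus (0.000141), conserved families 0.57 (0.00139) and developmental families 0.77 (0.0253, and 0.0625 with the replicate block), each with an adjusted p = 0.808 with an estimated correlation. Nutrient and stress families lay 0.52 (0.0253), families that target the small RNA machinery 1.08 (0.0207) and protein-coding genes 0.08 (0.0348, and 0.157 with the replicate block). With an estimated correlation these 3 had an adjusted p = 0.53, 0.52 and 0.808.

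**Figure D4:**
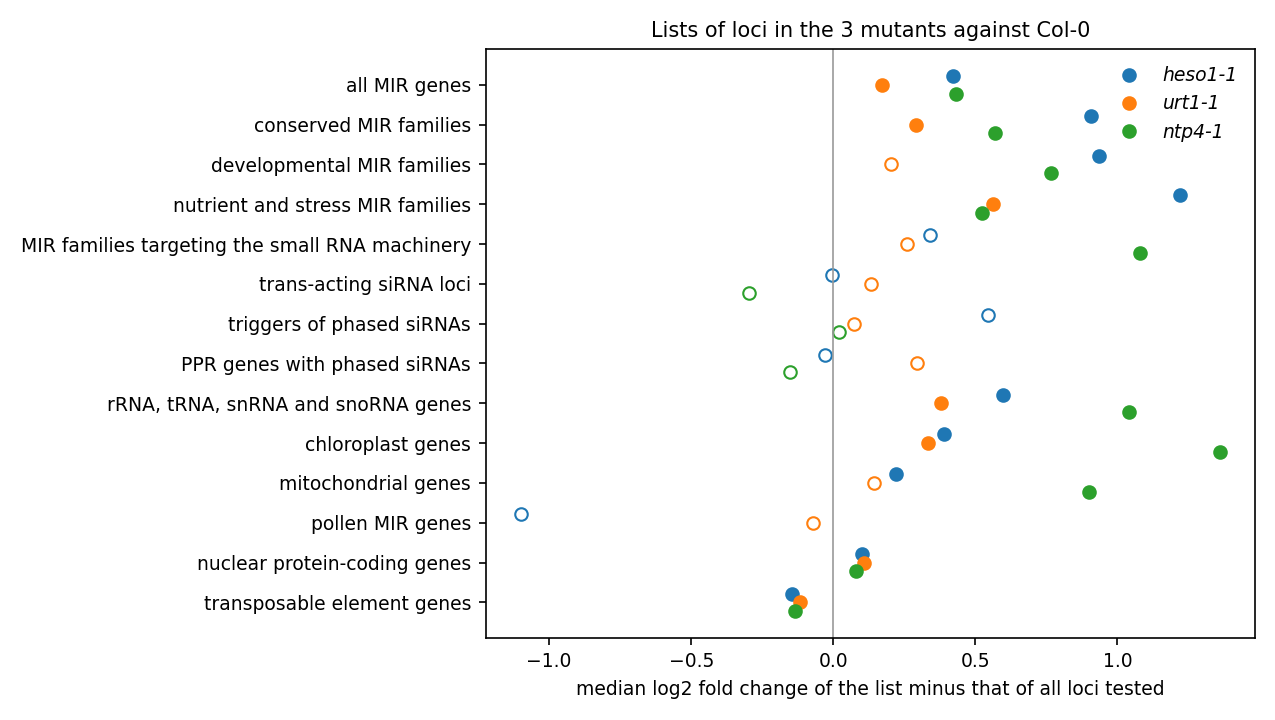
Median log2 fold change of each list of loci minus that of all loci tested, on the horizontal axis, for the 3 mutants against Col-0. Filled points passed camera with its preset correlation and open points did not; none passed with an estimated correlation, and the pollen list of ntp4-1 is absent because 2 of its members were tested.

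Of 209 MIR genes, 145 lay above the median locus in ntp4-1. On the deposited scale the median conserved MIR gene was at -0.23 and after TMM scaling at 0.39, where the calls of the conserved (adjusted p = 0.237), developmental (0.438), nutrient (0.264) and machinery lists (0.0897) and of protein-coding genes (0.152) ended. Adjusted over the list alone, 0 MIR genes rose and 6 of 209 fell, 4 of them in the conserved and in the developmental list: MIR165a, MIR165b, MIR166a and MIR319c. Over all loci none passed. The machinery list had a median of 0.28 and a mean of -0.05, with MIR162a at 44.3 ± 8.61 and 91.8 ± 35.9 RPM. The number of lists called was 6 without Col-0 replicate 1 and 5 without ntp4-1 replicate 2, against 10 of 13.

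The lists of the phased siRNA pathway did not pass in ntp4-1 (TAS loci adjusted p = 0.56, PPR genes 0.303, triggers 0.625). TAS1C was at 4079 ± 281 RPM in Col-0 and 1287 ± 378 RPM in ntp4-1 (adjusted p = 0.118, 0.00521 with the replicate block and 0.227 after TMM scaling). TAS1B was at 442 ± 86.7 and 153 ± 57.8 RPM, TAS1A at 871 ± 257 and 330 ± 187 RPM and TAS2 at 2349 ± 564 and 1253 ± 674 RPM (adjusted p = 0.0193, 0.0139 and 0.0346 with the block, and 0.296, 0.282 and 0.798 after TMM scaling), and TAS3 at 498 ± 249 and 467 ± 347 RPM. Relative to the median locus TAS2 was at -0.27 and TAS3 at 0.29. Adjusted over the list alone, TAS1C and TAS1B were lower (2 of 8) and so was the PPR gene AT1G63080 (1 of 11), at 807 ± 345 and 83.0 ± 60.1 RPM (0.00324 with the block and 0.0618 after TMM scaling). The pollen MIR genes MIR845a (1472 ± 723 and 383 ± 238 RPM) and MIR845b (531 ± 65.2 and 207 ± 49.02 RPM) were both lower adjusted over the list alone, and neither passed over all loci (adjusted p = 0.127 and 0.123, and 0.00365 and 0.0172 with the replicate block). After TMM scaling it was 0.602 and 0.724, with log2 fold changes of -1.23 and -0.52 against -2.08 and -1.38 as deposited.

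Several loci were called in more than 1 mutant. In heso1-1 and urt1-1 both, 6 bins rose and 12 fell, where independent lists would share 0.00547 and 0.0167. Unchanged groups simulated against a shared control shared a median of 0 and at most 2 bins over 50 draws. The simulated groups and their control were drawn from the residuals of all 12 libraries, not from the Col-0 values. Loci shared by heso1-1 and urt1-1 were 2 up (AGL23 and AT3G09960) and 2 down (AT3G22955 and AT5G42410), against 0.00685 and 0.00268 for independent lists and 0 in every simulated draw. For heso1-1 and ntp4-1 the shared bins were 1 up and 3 down (0.000158 and 0.00993), and for urt1-1 and ntp4-1 1 up and 8 down (0.00048 and 0.0339). The covariance of log2 fold changes over bins was 0.162, 0.216 and 0.177 in these 3 pairs against 0.162 simulated, and over loci 0.222, 0.247 and 0.225 against 0.144. The 3 Col-0 libraries were not split between the comparisons, so part of the excess may come from them.

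The mutants were also tested against each other. Between urt1-1 and heso1-1 limma called 2 bins and 0 loci (246 loci at an unadjusted p under 0.05), between ntp4-1 and heso1-1 17 bins (8 higher and 9 lower in ntp4-1) and 0 loci (5.93% of those tested at an unadjusted p under 0.05), and between ntp4-1 and urt1-1 25 bins (9 and 16) and 4 loci, all lower in ntp4-1. These 4 were EBF1 (log2 difference -4.44, adjusted p = 0.0129), GRF5 (-5.08, 0.0219), AT4G28920 (-4.43, 0.0219) and AT5G20700 (-3.25, 0.0435). The numbers of heso1-1 and ntp4-1 were also taken as pairs, although replicates 2 and 3 of heso1-1 correlated better with the other number of ntp4-1. With the replicate block 304 bins (51 higher and 253 lower in ntp4-1) and 52 loci (9 and 43) differed between them. With TMM scaling added these were 66 bins (37 and 29) and 7 loci (4 and 3). Of the 25 loci that rose in urt1-1, all 25 had a higher mean in heso1-1 than in Col-0 and 16 had every heso1-1 library above every Col-0 library, with a median log2 fold change of 1.53 against 2.91 in urt1-1 and 0 direct differences (lowest adjusted p = 0.999). In ntp4-1, 16 of the 25 had a higher mean than in Col-0 and 8 were without overlap, with a median of 0.12. These loci were chosen against the same Col-0 libraries, which raises such agreement by an amount that was not computed.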

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

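The tests with scaling to listed reads, with library sets and of miRNA arms, and the compartment shares without the rDNA bins or as deposited RPM, were chosen after the data were seen. Lists called by camera kept their direction under all scalings, while single calls and counts of calls moved with scaling, filter and library. The cause was not tested for any change below. Where a group keeps 1 library in a subset, that library is assumed to vary like the other groups. Depth limits loci of a few RPM: in heso1-1 replicate 3, with 2761330 implied reads, 1 RPM is fewer than 3 reads.

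For heso1-1 against Col-0, where 23 bins were called, the count was 12 with a pseudocount of 0.1 RPM, 93 with no filter, 5 with a mean of at least 5 RPM, 14 with median ratio scaling, 13 with TMM scaling, 35 scaled to listed reads, 14 with the replicate block and 14 with the replicate block and TMM scaling. Within library set B it was 11, and 10 with TMM scaling; edgeR called 0 (1624 at an unadjusted p under 0.05) and DESeq2 94. Leaving out 1 library gave 12 to 30. Of loci, 4 were called by limma: 0 with the replicate block (1584 at an unadjusted p under 0.05), 1 with the replicate block and TMM scaling, 9 within library set B and 7 with TMM scaling there, 2 by edgeR and 65 by DESeq2, and 3 to 11 with 1 library left out.

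For urt1-1 against Col-0, where 78 bins were called, the count was 46 with a pseudocount of 0.1 RPM, 152 with no filter, 14 with a mean of at least 5 RPM, 136 with median ratio scaling, 136 with TMM scaling and 145 scaled to listed reads. With the library set as a term it was 1696, and 1371 with TMM scaling. Within library set B it was 1763, and 2904 with TMM scaling; within set A limma called 0 (1956 at an unadjusted p under 0.05), edgeR called 1 and DESeq2 199. Leaving out 1 library gave 21 to 123. Of loci, 34 were called: 12 with a mean of at least 5 RPM, 88 with median ratio scaling, 82 with TMM scaling, 72 scaled to listed reads, 377 with the library set as a term and 331 with TMM scaling added, 120 within set B, 17 within set A, 10 by edgeR and 123 by DESeq2, and 9 to 47 with 1 library left out.

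For ntp4-1 against Col-0, where 30 bins were called, the count was 2 with a pseudocount of 0.1 RPM, 143 with no filter, 6 with a mean of at least 5 RPM, 10933 with the replicate block and 516 with TMM scaling added to it. With the library set as a term it was 13075, and 1396 with TMM scaling. Within library set B it was 7964, and 3648 with TMM scaling; edgeR called 0 (2300 at an unadjusted p under 0.05) and DESeq2 144. Leaving out 1 library gave 0 to 2924. Of loci, limma called 0 (1981 at an unadjusted p under 0.05, and 0 by edgeR): 2 with a pseudocount of 1 RPM, 102 with median ratio scaling, 102 with TMM scaling, 3 scaled to listed reads, 1559 with the replicate block, 333 with TMM scaling added to it, 2853 with the library set as a term, 619 with TMM scaling added, 1888 within set B, 790 with TMM scaling there, 1.7e2 by DESeq2 (145 up and 27 down) and 2 where any overlap puts a bin in a gene. Leaving out 1 library gave 0 to 749.

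Lists called numbered 9 of 14 in heso1-1, 7 of 14 in urt1-1 and 10 of 13 in ntp4-1 by camera, and 0 in each with an estimated correlation and 0 in each by fry. In urt1-1 they numbered 4 with no filter, 4 with median ratio scaling and 4 with TMM scaling, and in ntp4-1 6, 5 and 5. With 1 library left out they numbered 8 to 11 in heso1-1, 4 to 7 in urt1-1 and 5 to 10 in ntp4-1. Over the single list tests, 252, 246 and 206 alternatives in heso1-1, urt1-1 and ntp4-1 kept the direction and the side of the threshold, 26, 35 and 59 lost the call, 10, 8 and 2 gained it, and 0 reversed with a call on both sides. Another 5, 18 and 6, without a call, changed direction. Of the lost calls 2, 6 and 5 changed direction too: 2, 5 and 5 by fry, which does not compare a list with other loci, and chloroplast genes of urt1-1 without Col-0 replicate 1. For loci and bins named in the text, 849, 1008 and 559 kept both, 69, 265 and 61 lost the call, 19, 13 and 235 gained it, and 30, 54 and 27 changed sign without a call. In urt1-1, 1 changed sign with a call: TAS3 at 0.82 (adjusted p = 0.0287) with the library set as a term and TMM scaling. In ntp4-1, 2 did: MIR158a at 0.70 (adjusted p = 0.0414) and TAS3 at 0.65 (adjusted p = 0.0437) within library set B with TMM scaling.

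Shares of compartments moved with the bins counted. The arms of heso1-1 differed from Col-0 by 1.84 points without the bins at the chromosome 3 rDNA and by -3.51 as deposited RPM. The pericentromere of heso1-1 differed by 2.47 when narrowed, by -0.101 without the 10 highest bins, by -2.58 without the rDNA bins and by -1.96 as deposited RPM. In urt1-1 the arms differed by -4.51 as deposited RPM, and the pericentromere by -0.331 when narrowed, -1.38 without the 10 highest bins, -3.67 without the rDNA bins and -4.90 as deposited RPM. In ntp4-1 the arms differed by -8.48 with narrowed pericentromeres, -2.67 without the 10 highest bins, -2.35 without the rDNA bins and -10.9 as deposited RPM. Its pericentromere differed by 0.931 when narrowed, -6.94 without the rDNA bins and -8.31 as deposited RPM, its chloroplast by 2.55 without the 10 highest bins, 8.30 without the rDNA bins and 1.83 as deposited RPM, and its mitochondrion by 0.12 as deposited RPM. Of the shares apart from Col-0, these then overlapped it: the pericentromere of heso1-1 without the 10 highest bins, without the rDNA bins and as deposited RPM, that of urt1-1 narrowed and as deposited RPM, that of ntp4-1 narrowed and without the 10 highest bins (-0.911), its chloroplast without the 10 highest bins and as deposited RPM, and its mitochondrion as deposited RPM.

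Arm ratios called numbered 1 in heso1-1 within library set B, against 0, and in urt1-1 11 within set B and 1 with the library set as a term, against 0. In ntp4-1, against 6, they numbered 4 with a pseudocount of 0.1 RPM, 14 within set B and 15 with the library set as a term. They numbered 14 with the replicate block and 14 with the block and without the requirement of a whole mature sequence. With 1 library left out they were 0 to 6.

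The numbers of Col-0 and urt1-1 replicates do not pair the libraries: the correlations of their deviations were 0.39, 0.45 and -0.28, and not every library correlates best with that of its own number, a hint from the data and not the design. With the replicate block 237 bins and 27 loci were called there. Of the results named for heso1-1 and ntp4-1, the replicate block changed no call other than those given.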

Other observations

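The sums over every listed bin that a locus with the same mature sequence touches add to the arm results. The bins with miR165-3p summed to 160 ± 41.2 RPM in Col-0, 16.6 ± 1.99 RPM in ntp4-1 and 64.6 ± 15.1 RPM in urt1-1, and those with miR166-3p to 2092 ± 540.5, 317 ± 71.1 and 894 ± 235 RPM. All libraries of ntp4-1 and urt1-1 lay below those of Col-0 in both, while heso1-1 overlapped Col-0. At the chloroplast, the bins at 141401 to 141500 and 97101 to 97200 were at 4219 ± 764 and 4218 ± 714 RPM in Col-0 and 7790 ± 10.03 and 7753 ± 42.2 RPM in ntp4-1. Library by library these bins had nearly the same values, such as 7780 and 7724 RPM in ntp4-1 replicate 1. They are therefore not taken as separate results. The same held for the bins at 104601 to 104700 and 134001 to 134100, and all of these bins count in the chloroplast share.

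All tests in this part were chosen only after the result was seen. The first pattern is the fall of the 3p relative to the 5p bins of miR165a, miR166e, miR168a and miR171b in ntp4-1. A scaling factor cancels in the ratio of 2 bins of a library only where both lie far above the pseudocount. For miR171b it cancels only in part, since its bins were at 0.263 (3p) and 0.395 (5p) RPM in ntp4-1 replicate 1. With a pseudocount of 0.1 RPM 4 arm ratios were called in ntp4-1, against 6. Within library set B the median ratio change was -1.99. That value decides nothing about library sets, since the precursors were chosen by calls in a fit that holds the same libraries. Col-0 and ntp4-1 also divide alike, with replicate 1 in set A and replicates 2 and 3 in set B. Placement of reads between loci with the same mature sequence is argued against for miR165a and miR166e, since the summed 3p bins fell by at least 2.71 in log2 (-2.71), and cannot be told apart for miR171b (-1.71, SE 1.34, over its 2 loci). Whether loss of NTP4 lowers these 3p strands stays open, because no rescued line or second mutant line is in the series.

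The second pattern is the 23 bins called in the same direction in 2 or 3 mutants, 4 of them in 3. Chance values of the shared Col-0 libraries could not be excluded. heso1-1 and urt1-1 share 18 bins where simulated groups shared at most 2. The simulated control, however, was drawn from the residuals of all 12 libraries, so the Col-0 values themselves did not enter it. Over all bins the covariance of heso1-1 and urt1-1, 0.162, equals the simulated one. Col-0 plants that differ from all 3 mutant lines are argued against for 3 bins, where ntp4-1 overlaps Col-0 and differs from heso1-1 and from urt1-1 in direct tests. For the other 20 a difference of the Col-0 plants cannot be told apart from an effect of the mutants, because every comparison uses the same Col-0 libraries.

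The third pattern is the lower median bin of ntp4-1. Scaled to listed reads the median was still -0.377, but over 63040 bins past the filter against 39696 as deposited. The part due to reads outside the listed bins can therefore not be read from the 2 medians. The chloroplast share accounts for a shift of -0.0277. That shift is a small part of the deposited median of -0.749, while the part due to reads outside the listed bins stays open. No biological explanation was tested.

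With 10 splits of 6 libraries into 3 and 3, no share under 0.05 can be reached, and the number of splits with as many calls as the real one follows, the real one included. In heso1-1 it was 1 for bins (23 calls, highest other 3), 1 for loci (4 and 2), 1 for lists (9 and 8) and 10 for arm ratios (0 by limma in all). In ntp4-1 it was 4 for bins (30 and 96), 10 for loci (0 and 36), 1 for lists (10 and 7) and 1 for arm ratios (6 and 1). In urt1-1 it was 2 for bins (78 and 11101), 2 for loci (34 and 627), 3 for lists (7 and 8) and 10 for arm ratios (0 and 5). The split with 11101 bins and 627 loci sets Col-0 replicate 1 with urt1-1 replicates 1 and 3, the members of library set A, against the rest, which points to a structure of the samples that no label names.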
